A study of Bos taurus with 8 samples.

How the data were processed

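Gene expression was measured in cultured bovine mammary epithelial cells on 8 one-colour Agilent arrays: 3 with the EEF1D-1357 shRNA, 3 with the EEF1D-1893 shRNA and 2 controls without shRNA. Per the file headers, the scanner values are Cy3 spot intensity values from Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. Per the file headers, the processed intensity is background-subtracted and spatially detrended, carries a surrogate value for spots near background and is not normalized between arrays. The other columns that were used are 0 or 1 flags per spot, given per the file headers for signal well above background, saturation and outlier spots. The deposited table of the series holds log2 values of the processed intensity, averaged over the spots of a probe and quantile normalized. Its median was 7.55 in each of the 8 arrays, and its correlation over probes with the scanner values of the same array lay between 0.998 and 1.000. That table was used only as an alternative source.

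Of 43653 probes that are not controls, 214 were left out because a spot was an outlier on at least 1 array, which left 43439. Probes were named with the RefSeq gene table of ARS-UCD2.0, which was used for names alone: 26510 by the probe's own accession, 6445 by the symbol in the files, 604 by another accession and 160 by an older symbol. A further 568 kept the symbol in the files and 9152 had no gene name. Each array's log2 processed intensity was reduced by that array's 75th percentile. Probes well above background on at least 2 arrays were kept (30723, of which 25558 were named). Of each gene, the probe with the highest mean over the 8 arrays was taken. This gave 12618 genes, of which 7462 had more than 1 probe to choose from.

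A model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0. It had 5 residual degrees of freedom, and limma added 2.13 from the spread of the other genes. The contrasts were the mean of both shRNA groups against the controls, each shRNA against the controls, and EEF1D-1357 against EEF1D-1893. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and tests were two-sided. Gene lists (33, each with at least 5 measured members) were tested with camera of limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the 33 lists. The camera test compares the members of a list with all other genes. Within each list, members were also counted with p-values adjusted over the list alone. The lists, the contrasts, the tests and the rule for named genes were set before the data were examined. The lists cover translation, milk synthesis, signalling, stress, the cell cycle and markers of 6 cell types.

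The genes to name were EEF1D with each of its probes, then up to 10 called genes in each direction for both shRNAs against control and up to 5 in each direction for the other contrasts, ranked by log2 fold change. They had to be well above background in most arrays and to keep the groups apart. Where no gene was called, the 5 with the smallest p-value were named as not passing. The rule also names up to 4 members of each list described, by p-value, and up to 3 genes in each direction that were at background on one side, by the lower bound of their fold. That bound sets the arrays at background to the lowest signal that was well above background.

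The file headers place the arrays on 2 slides. Slide 1 held the 3 EEF1D-1357 arrays and control replicate 2, and slide 2 held the 3 EEF1D-1893 arrays and control replicate 1. Each contrast was also fitted with slide as a block, which compares each shRNA with the control on its own slide. In that model all 4 residual degrees of freedom come from the shRNA arrays, so the difference between the controls is not part of its spread. Because both shRNA contrasts share 2 control arrays, their overlap was set beside 100 simulations of unchanged shRNA groups against shared controls.

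The alternatives tried were normexp background correction (offset 50) with quantile normalization, quantile normalization, scaling by the median, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, each probe as its own feature, the deposited table, a prior with an intensity trend and robust fit, array weights, only the compared groups, replicate number or slide as a block, other thresholds, an estimated correlation for lists, and each array left out in turn. A further 3 were chosen after seeing the data: control replicate 1 and EEF1D-1357 replicate 3 both left out, the slide block without EEF1D-1357 replicate 3, and each slide on its own. The workflow was tested on simulated data with independent normal noise and 100 genes changed at each of 2 sizes. At a log2 change of 1 it recovered 47 genes for both shRNAs against control, 26 and 19 for EEF1D-1357 and EEF1D-1893 against control, and 47 between the shRNAs. At a log2 change of 2 it recovered 83, 79, 81 and 90. False calls numbered 9, 3, 3 and 3 over both sizes, and a planted list was called for both shRNAs against control, beside 1 list that was not planted. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Some results on single genes are not reported here.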

Results

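Transcript levels were measured on bovine gene expression arrays in primary mammary epithelial cells that came from the tissue of a lactating Holstein cow and were used at the fifth passage. The cells carried a short hairpin RNA (shRNA), which lowers its target mRNA by RNA interference, against EEF1D, or by their labels no shRNA. EEF1D encodes the delta subunit of translation elongation factor 1, part of the guanine nucleotide exchange complex that recharges eEF1A during translation. There were 3 arrays with the EEF1D-1357 shRNA, 3 with the EEF1D-1893 shRNA and 2 control arrays. The labels name no array with a non-targeting shRNA, so an effect of introducing an shRNA cannot be separated from the loss of EEF1D. Whether the controls carried a negative control construct is uncertain, and this limit holds if they did not. Between 60.7% and 71.6% of the probes were well above background per array, the 75th percentile of the signal lay between 1276 and 2102 intensity units, and 0 spots were saturated. The number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays.

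The control arrays differed from each other more than any pair of arrays with the same shRNA. The SD over 12618 genes of the log2 difference was 0.83 between the controls and lay between 0.50 and 0.73 within the shRNA groups. Control replicate 1 had the lowest median correlation over genes with the other arrays (r = 0.968, against 0.976 to 0.981). Its 75th percentile was the 1276 units above, and its labelled spike-in controls stood 1.29 log2 units over that percentile, against 0.27 to 0.76 in the other 7 arrays. The controls also lay on different slides. Slide 1 held the EEF1D-1357 arrays with control replicate 2, and slide 2 held the EEF1D-1893 arrays with control replicate 1.

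**Figure D1:**
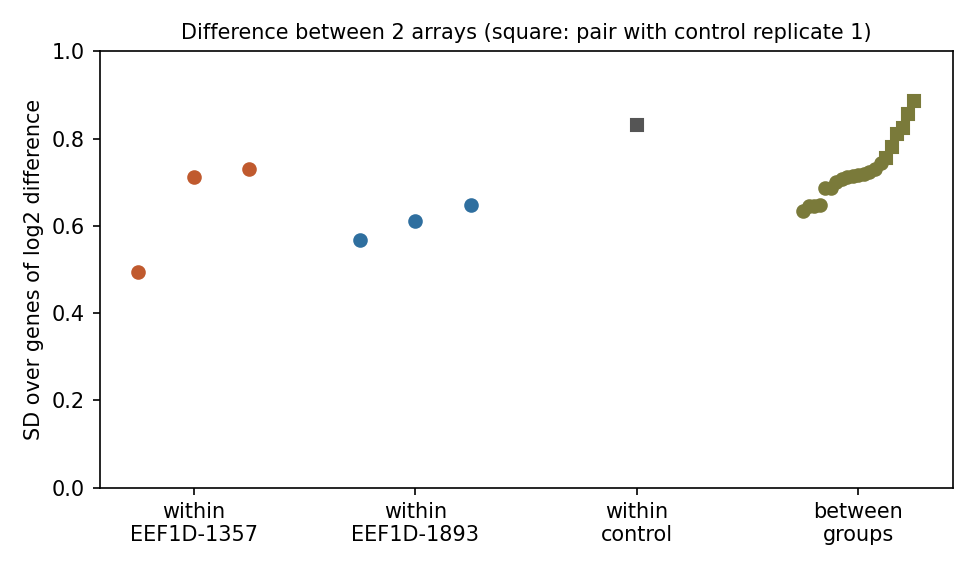
SD over genes of the log2 difference between 2 arrays, by the groups of the pair, with squares for pairs that include control replicate 1. The pair of controls stands at 0.83, above the pairs of arrays with the same shRNA (0.50 to 0.73).

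The target of both shRNAs, EEF1D, was measured below the control level, without passing the test. Its brightest probe, A_73_115715 on chromosome 14 from 938301 to 938360 (Btau_3.1), had a mean scaled log2 signal of 5.64 ± 0.48 (SD, n = 3) with EEF1D-1357, 5.83 ± 0.14 (n = 3) with EEF1D-1893 and 6.63 ± 0.69 (n = 2) in the controls. The log2 fold change of both shRNAs against control was -0.89 (SE 0.32), or 53.8% of control (limma adjusted p = 0.243). With EEF1D-1357 it was -0.99 (SE 0.36), or 50.4% of control (adjusted p = 0.263). With EEF1D-1893 it was -0.80 (SE 0.36), or 57.5% of control (adjusted p = 0.374). All 6 shRNA arrays, at 5.09 to 5.99, lay below both controls, at 6.14 and 7.11. Within the slides EEF1D stood at 70.7% of control with EEF1D-1357 and at 41.0% with EEF1D-1893 (slide block adjusted p = 0.557 and 0.063), and at 53.8% over both (adjusted p = 0.0873). On slide 1 EEF1D-1357 replicates 1 and 2, at 5.97 and 5.85, lay nearer to control replicate 2 (6.14) than replicate 3 did (5.09). With replicate 3 left out, the log2 fold change against that control was -0.23. The size over all arrays rested on control replicate 1: without it the log2 fold changes were -0.41 over both shRNAs, -0.50 with EEF1D-1357 and -0.31 with EEF1D-1893. Without control replicate 2 they were -1.38 (adjusted p = 0.0376), -1.48 (adjusted p = 0.0373) and -1.29, and the first 2 passed.

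The other 3 EEF1D probes pointed downwards as well over both shRNAs, against the mean of both controls. A_73_P279701, which overlaps the brightest probe (938160 to 938333), had a log2 fold change of -0.88 (SE 0.31). A_73_P159712, at 934089 to 934148, had -1.16 (SE 0.48), with EEF1D-1357 replicate 3 lowest at a scaled log2 signal of -2.08. EEF1D-1893 replicate 1 (-0.09) lay above control replicate 2 (-0.22) in this probe, and the other shRNA arrays lay below both controls. A_73_P265551, at 931228 to 931287, had -0.33 (SE 0.33), and its spot was not well above background in EEF1D-1357 replicate 3. Within slide 1 this dim probe was 0.14 log2 units above the control. Control replicate 2 (-5.26) lay below all EEF1D-1893 arrays (-4.79 to -4.65) and EEF1D-1357 replicates 1 and 2 (-5.02 and -4.95), but above EEF1D-1357 replicate 3 (-5.39). The downward direction of A_73_P265551 thus rested on control replicate 1 (-3.91). The positions of the shRNA target sites are not given in the labels, so no probe could be placed relative to them. Of the 7 measured members of the elongation factor list 6 had lower values, with no call. Among them were EEF1A1 at -0.26, EEF2, which lies outside the eEF1 complex, at -0.31 and EEF1B2 at -0.25 (limma p adjusted over the list alone 0.175, 0.175 and 0.197). EEF1D is itself among the lower members, so the count includes the target. Without control replicate 1 EEF2 stood at -0.08 and EEF1B2 at -0.11.

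**Figure D2:**
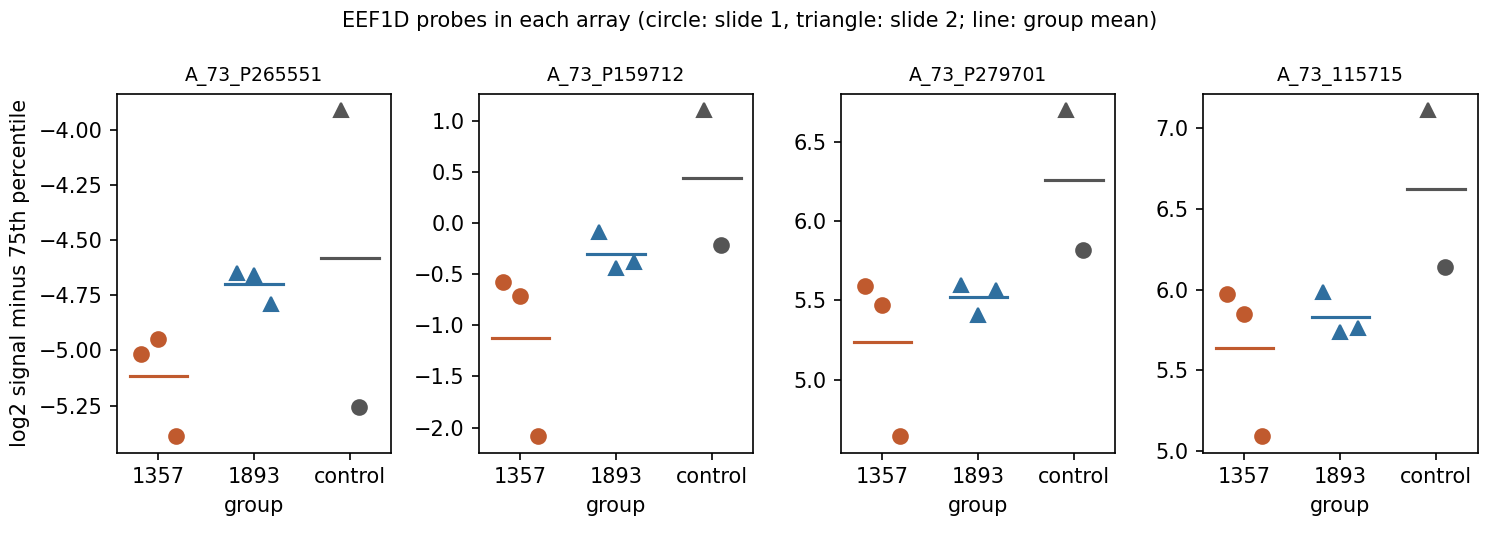
Scaled log2 signal of the 4 EEF1D probes in each array, ordered along chromosome 14 with a separate vertical axis each, with points for arrays and lines for group means. For the brightest probe, A_73_115715, the shRNA arrays sit at 5.09 to 5.99 and the controls at 6.14 and 7.11.

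The arrays of both shRNAs together were compared with both controls. Genes of endoplasmic reticulum (ER) chaperones and the unfolded protein response, which fold and clear secretory proteins, were higher as a group, and so were heat shock protein genes and genes of NF-kB signalling and inflammatory cytokines. Genes of mitosis, DNA replication, cholesterol synthesis and cytosolic ribosomal proteins were lower as groups. These 7 of 33 lists were called by camera with its preset correlation. With an estimated correlation 0 lists were called (adjusted p = 0.772 with an estimated correlation for each of the 7).

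The ER chaperone list had a median log2 fold change of 0.30, with 22 of 24 measured members above 0 (adjusted p = 1.32e-05). Adjusted over the list alone, 2 members rose: DNAJB9, a co-chaperone of the ER chaperone BiP, by 0.79 (SE 0.15) and XBP1, a transcription factor of the unfolded protein response, by 0.62 (SE 0.13) (limma adjusted p = 0.0285 for each). Over all genes 0 members passed. DNAJB11 (0.47) and SYVN1 (0.45, or 0.25 without control replicate 1) did not pass in either way. The list stood higher in all 6 shRNA arrays than in both controls, and its median within slides 1 and 2 was 0.29 and 0.26. Without control replicate 2 it was 0.18 (adjusted p = 0.0109). Heat shock genes had a median of 0.15, with 20 of 28 members above 0 (adjusted p = 0.0193). None of them passed adjusted over the list alone (0 members by limma, 4 at an unadjusted p under 0.05). DNAJB4 (0.75) and HSPE1 (0.33) had the smallest p-values. The heat shock median was 0.22 within slide 1 and 0.04 within slide 2, and without control replicate 2 it was 0.06 with no call (adjusted p = 0.201), against 0.24 without control replicate 1.

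Inflammatory genes had a median log2 fold change of 0.42, with 27 of 36 members above 0 (adjusted p = 0.00351). Adjusted over the list alone, the neutrophil chemokine CXCL8 rose by 2.33 (SE 0.54), the chemokine CCL20 rose by 2.97 (SE 0.70) and the receptor TLR2 fell by 0.70 (SE 0.17), with limma adjusted p = 0.0495 for each, whereas 0 members passed over all genes. With the mean of its probes TLR2 stood at 0.07. IL1A stood at 1.13, or 0.61 without control replicate 1, and did not pass. The list's median was 0.52 within slide 1 and 0.09 within slide 2. Without control replicate 1 it was 0.36 with no call (adjusted p = 0.493), and without EEF1D-1357 replicate 2 or EEF1D-1893 replicate 3 it was 0.22 or 0.24 with the call kept.

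The mitosis list had a median log2 fold change of -0.81, with 43 of 45 members below 0 (adjusted p = 0.000192). The kinase NEK2 stood at -1.23 (SE 0.34), the cytokinesis protein ANLN at -1.66 (SE 0.47) and the kinetochore protein CENPF at -1.56 (SE 0.52). The DNA replication list had a median of -0.43, with 36 of 42 members below 0 (adjusted p = 0.0218), among them CDC45 at -1.11 and POLA2 at -0.99 (-0.61 without control replicate 1). In both lists 0 members passed, over all genes or adjusted over the list alone (limma; 6 mitosis and 4 replication genes were lower at an unadjusted p under 0.05, and 2 replication genes higher). Within slides 1 and 2 the medians were -0.93 and -0.48 for mitosis and -0.42 and -0.46 for replication. The arrays were not uniform: mitosis genes were lowest in EEF1D-1357 replicates 1 and 2, at -1.30 and -0.76 log2 units from the mean of the 8 arrays, while EEF1D-1357 replicate 3 (0.42) and EEF1D-1893 replicate 3 (0.73) lay near or above the controls (0.57 and 0.44). Without control replicate 2 neither list was called, at medians of -0.92 (adjusted p = 0.209) and -0.77 (adjusted p = 0.201). The replication list also lost its call without control replicate 1 (-0.18, adjusted p = 0.29), EEF1D-1357 replicate 1 (-0.30, adjusted p = 0.0693) or EEF1D-1893 replicate 2 (-0.35, adjusted p = 0.0705), and with slide as a block (adjusted p = 0.0669).

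Cytosolic ribosomal protein genes had a median log2 fold change of -0.19, with 75 of 78 members below 0 (adjusted p = 0.000192), and 0 members passed adjusted over the list alone (limma; 1 at an unadjusted p under 0.05). RPL13A, at -0.41 (-0.21 without control replicate 1), had the smallest p-value. This shift depended on the scaling: the median was -0.02 with quantile normalization (adjusted p = 0.621) and -0.11 with median scaling (adjusted p = 0.00635). It was -0.08 within slide 1 and -0.31 within slide 2, and without control replicate 1 it was at 0.00 with the sign turned (adjusted p = 0.493), while without control replicate 2 it was -0.39. Cholesterol synthesis genes had a median of -0.44, with 16 of 23 members below 0 (adjusted p = 0.0457). INSIG1, which retains SREBP in the ER, stood at -0.86 (SE 0.19) and lanosterol synthase LSS at -0.69 (SE 0.18, or -0.38 without control replicate 1), neither passing adjusted over the list alone (limma adjusted p = 0.0636 and 0.0678; 0 members passed, 7 were lower and 1 higher at an unadjusted p under 0.05). The list's median was 0.03 within slide 1 and -0.91 within slide 2. The call was lost with slide as a block (adjusted p = 0.0543), and without control replicate 1 (-0.06, adjusted p = 0.493), EEF1D-1357 replicate 1 (-0.43, adjusted p = 0.0693), EEF1D-1893 replicate 1 (-0.37, adjusted p = 0.0765) or EEF1D-1893 replicate 2 (-0.39, adjusted p = 0.0581). Without control replicate 2 the median was -0.85.

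**Figure D3:**
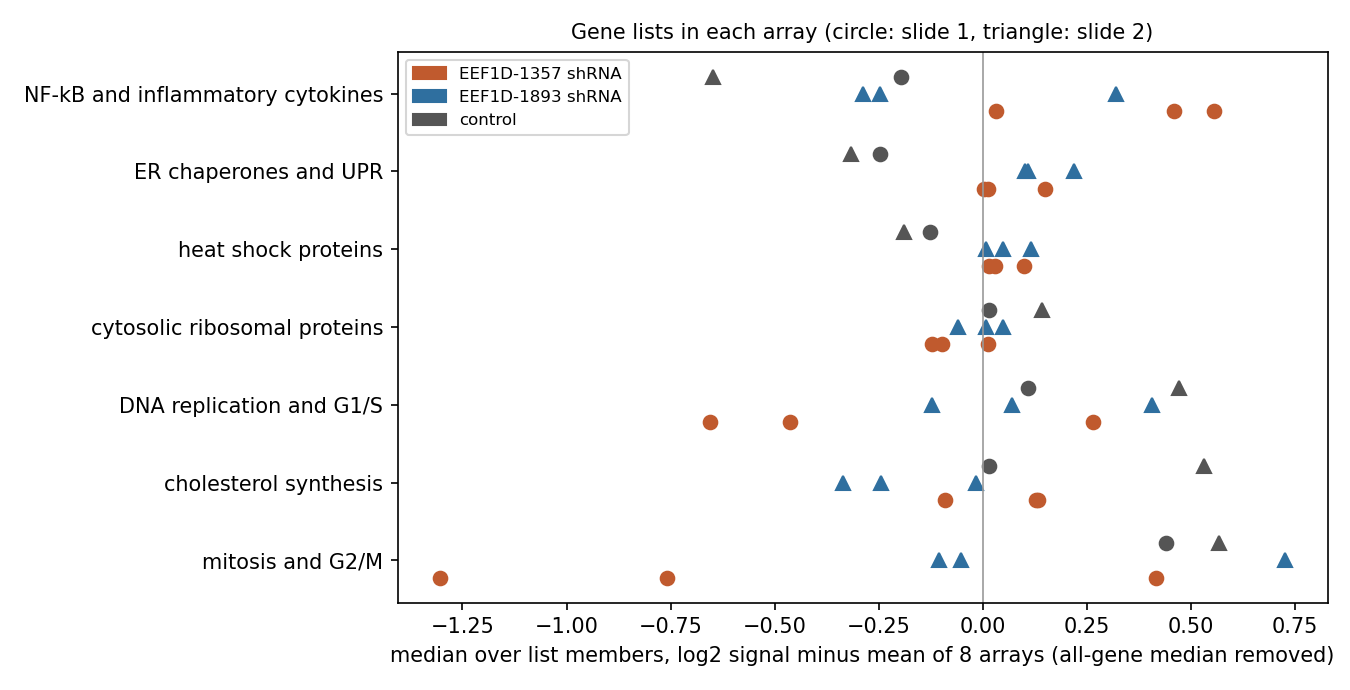
Median over the members of each called list of the log2 signal of an array minus the mean of the 8 arrays, after removal of each array's all-gene median, with points for arrays. ER chaperone genes sit at 0.00 to 0.22 in the shRNA arrays and at -0.32 and -0.25 in the controls, and mitosis genes spread from -1.30 to 0.73 in the shRNA arrays.

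Lists for milk synthesis and signalling were not called, but held single genes that passed adjusted over the list alone in limma. In the milk fat list (median -0.16, adjusted p = 0.224) 3 of 47 members fell: fatty acid synthase FASN by 0.80 (SE 0.15), the acetyl-CoA carboxylase gene ACACA by 0.85 (SE 0.18) and the fatty acid transporter SLC27A3 by 0.92 (SE 0.16). NFIB, in the prolactin and STAT5 list (median -0.01, adjusted p = 0.658), fell by 0.80, and FOXO1, in the PI3K, AKT and mTOR list (median -0.15, adjusted p = 0.384), fell by 0.70. In the apoptosis list (median 0.03, mean -0.04, adjusted p = 0.362) cytochrome c (CYCS) rose by 0.75, CASP6 rose by 0.67 and the survival gene BCL2 fell by 1.23 (SE 0.29). Without control replicate 1 CASP6 stood at 0.39 and BCL2 at -0.67. None of these 8 genes passed over all genes, where their adjusted p lay between 0.135 and 0.163. Milk protein genes gave no call (median -0.06, mean 0.16, adjusted p = 0.988), and casein beta (CSN2) stood at -0.36 and beta-lactoglobulin (PAEP) at -0.21. Without control replicate 1 CSN2 was at -0.02 and PAEP turned to 0.06.

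Of the other lists for translation and stress, the elongation factors (median -0.25, camera adjusted p = 0.0928), aminoacyl-tRNA synthetases (-0.17, 0.0763), initiation factors (0.03, 0.496) and the integrated stress response (-0.32, 0.0525) were not called. Of 22 alternatives, 11 called the stress response and 8 the synthetases. Interferon-stimulated genes, which respond to double-stranded RNA, stood at a median of -0.15 (adjusted p = 0.758), and the small RNA pathway at -0.11 (0.534). Mitochondrial ribosomal proteins (0.07, 0.0517), oxidative phosphorylation (0.04, 0.084), proteasome subunits (0.09, 0.0517), p53 targets (0.16, 0.0557), NRF2 targets (-0.15, 0.539) and TGF-beta targets with extracellular matrix (0.10, 0.342) were not called either, though 8 alternatives called mitochondrial ribosomal proteins, 7 the proteasome and 6 the p53 targets. Nor were the metabolic lists: PPAR and AMPK signalling (-0.09, 0.606), amino acid transporters (-0.23, 0.758) and glucose uptake with glycolysis (-0.09, 0.509).

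Markers of 6 cell types did not shift as groups. The medians were -0.20 for luminal epithelium (adjusted p = 0.393), -0.14 for basal and myoepithelial cells (0.318), -0.30 for fibroblasts (0.524), -0.27 for endothelium (mean 0.01, 0.534), -0.15 for leukocytes (0.606) and -0.01 for adipocytes (mean 0.03, 0.988). Adjusted over the list alone in limma, the oxytocin receptor OXTR fell by 2.04 (SE 0.23, adjusted p = 0.000751) and CD3D, part of the T cell receptor complex, fell by 0.63 (SE 0.15, adjusted p = 0.0353). OXTR was well above background on 2 arrays, both controls, so its fall is better given as at least 2.27-fold lower. The smooth muscle kinase MYLK stood at -3.50 (SE 0.92) and did not pass (adjusted p = 0.056).

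No single gene passed over all 12618 genes for both shRNAs against control (0 in limma, smallest adjusted p = 0.0526). At an unadjusted p under 0.05 there were 2137 genes, 926 higher and 1211 lower, where chance gives 630.9. With the shRNA arrays taken as 1 group the real split gave 2141. Splits with control replicate 1 beside 1 shRNA array gave 684 to 1959, and with control replicate 2 instead 321 to 684. Much of the excess can thus come from control replicate 1. Of the genes with groups apart and signal well above background in both, the nearest to passing were all lower: the mitotic kinase NEK6 at -1.25 (SE 0.13), the Ras-like GTPase ERAS at -1.28 (SE 0.14) and the hexokinase-like HKDC1 at -1.90 (SE 0.20), each at adjusted p = 0.0526, then PRRG3 at -1.52 and the Wnt pathway kinase TNIK at -1.08 (adjusted p = 0.0737 for both). With slide as a block 719 genes passed, 339 up and 380 down, these 5 among them (adjusted p between 0.0183 and 0.0333), in a fit whose spread leaves out the difference between the controls. Leaving out control replicate 1 gave 26 genes and leaving out control replicate 2 gave 2928, with the remaining control assumed to vary like the shRNA groups. The share of higher genes at an unadjusted p under 0.05 was 43.3% and became 61.7% with median scaling. All shRNA arrays lay on one side of both controls in 16.9% of genes, where chance gives 7.14% if all arrays can be exchanged. Control replicate 1 stood apart from the other arrays, so part of this excess can come from it alone.

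With EEF1D-1357 alone, inflammatory genes were higher and cell division genes lower than in the controls, by more than in the comparison of both shRNAs. Replicates 1 and 2 carried this, at -1.30 and -0.76 for mitosis and 0.46 and 0.56 for inflammatory genes, from the mean of the 8 arrays. Replicate 3 stood at 0.42 and 0.03, although its EEF1D signal was lowest (5.09, against 5.97 and 5.85). These shifts were thus not larger where EEF1D was lower, whereas ER chaperones were highest in replicate 3 (0.15, against 0.00 and 0.01). The mitosis list had a median log2 fold change of -1.15 with 45 of 45 members below 0 (camera adjusted p = 1.36e-07), and ANLN stood at -2.12 (SE 0.53). None of the 8 lists given here was called with an estimated correlation (adjusted p = 0.857 with an estimated correlation for each). The replication list had a median of -0.68 (adjusted p = 0.000339). The inflammatory list stood at 0.62 with 30 of 36 members above 0 (adjusted p = 3.65e-06). Adjusted over the list alone, CXCL8 rose by 2.71 (SE 0.61), CCL20 rose by 3.30 (SE 0.79) and TLR2 fell by 0.86 (SE 0.19), with limma adjusted p = 0.0468 for each. ER chaperones (0.23, adjusted p = 0.000339) and heat shock genes (0.13, adjusted p = 0.0483) were higher. Ribosomal proteins (-0.26, adjusted p = 3.65e-06), aminoacyl-tRNA synthetases (-0.24, adjusted p = 0.0467, with MARS1 at -1.07, or -0.65 without control replicate 1) and the integrated stress response (-0.36, adjusted p = 0.0483, with PSAT1 at -1.38 and ATF4 at -0.54, or -0.24 for ATF4 without control replicate 1) were lower.

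Within slide 1 the medians were -0.93 for mitosis, -0.42 for replication, 0.52 for inflammatory genes, 0.29 for ER chaperones, 0.22 for heat shock, -0.08 for ribosomal proteins, -0.06 for synthetases and -0.14 for the stress response, of which heat shock, the synthetases and the stress response were not called in the slide block (adjusted p = 0.0506, 0.393 and 0.259). Leaving out control replicate 1 gave those same medians, and these 3 calls were lost there and without any single EEF1D-1893 array. The synthetases also lost theirs without EEF1D-1357 replicate 1 (-0.22, adjusted p = 0.107) or 2 (-0.20, adjusted p = 0.126), and the stress response without EEF1D-1357 replicate 1 (-0.32, adjusted p = 0.0591) or control replicate 2 (-0.68, adjusted p = 0.134). Heat shock lost its call without EEF1D-1357 replicate 2 (0.11, adjusted p = 0.111) or 3 (0.16, adjusted p = 0.0531), and turned to -0.02 without control replicate 2 (adjusted p = 0.271). Without control replicate 2 the replication list was not called either (-0.92, adjusted p = 0.0597), the inflammatory median was 1.00, the ER median 0.12 and the synthetase median -0.38, and without EEF1D-1357 replicate 1 the mitosis median was -0.76. Ribosomal proteins were at -0.04 with no call under quantile normalization (adjusted p = 0.609), and at -0.08 and -0.45 without control replicate 1 and 2. Median scaling moved the median of all genes from -0.09 to 0.03, and the share of higher genes at an unadjusted p under 0.05 from 38.4% to 61.8%.

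Among the genes that passed adjusted over their list alone with EEF1D-1357, SLC27A3 fell by 1.16, ACACA fell by 0.98, NFIB fell by 0.83 and FOXO1 fell by 0.78. Over all genes 0 passed in limma (smallest adjusted p = 0.0558; 2047 at an unadjusted p under 0.05, 786 higher and 1261 lower). The nearest by the same criteria were HKDC1 at -2.27 (SE 0.23), NEK6 at -1.45 (SE 0.15) and ERAS at -1.47 (SE 0.15), each at adjusted p = 0.0558. Next came the nuclear factor TOX at 2.61 (SE 0.33, adjusted p = 0.105) and the NAD synthesis enzyme QPRT at -1.08 (SE 0.15, adjusted p = 0.13). With slide as a block 28 genes passed, 4 up and 24 down, and with control replicate 1 or 2 left out 28 or 2912 passed. The groups were apart in 30.7% of genes, where chance gives 20% if the arrays can be exchanged, which leaves out that control replicate 1 stood apart.

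With EEF1D-1893 alone, ER chaperone genes were higher and lipid synthesis genes lower than in the controls. The ER chaperone list had a median log2 fold change of 0.34 with 22 of 24 members above 0 (camera adjusted p = 1.35e-06). None of the 6 lists given here as higher or lower was called with an estimated correlation (adjusted p between 0.725 and 0.79). Adjusted over the list alone, 3 members rose in limma: DNAJB9 by 0.76 (SE 0.17), XBP1 by 0.70 (SE 0.15) and DNAJB11 by 0.64 (SE 0.16). Cholesterol synthesis genes stood at -0.46 with 18 of 23 members below 0 (adjusted p = 0.00277), and INSIG1 fell by 1.13 (SE 0.22) and LSS fell by 0.99 (SE 0.20), both with limma adjusted p = 0.0179 over the list alone. Milk fat genes stood at -0.20 (adjusted p = 0.0309), and FASN fell by 0.92 (SE 0.16) and the acetyl-CoA synthetase ACSS2 fell by 0.77 (SE 0.16). Heat shock genes (0.18, adjusted p = 0.0192) and mitochondrial ribosomal proteins (0.12, adjusted p = 0.00512, with MRPL1 at 0.87) were higher, and cytosolic ribosomal proteins (-0.12, adjusted p = 0.0309) were lower. Outside these lists NFIB fell by 0.76 and STAT3 fell by 0.67, each adjusted over its list alone. Mitosis (-0.33, adjusted p = 0.17) and inflammatory genes (0.05, adjusted p = 0.349) were not called.

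Within slide 2 the medians were 0.26 for ER chaperones, -0.91 for cholesterol synthesis, -0.37 for milk fat, 0.04 for heat shock and -0.31 for cytosolic ribosomal proteins, and mitochondrial ribosomal proteins turned to -0.04. In the slide block milk fat, heat shock and mitochondrial ribosomal proteins were not called (adjusted p = 0.159, 0.159 and 0.396), nor were they without control replicate 2, which gave the same medians for all 6 lists. Without control replicate 1 cholesterol synthesis was not called (-0.24, adjusted p = 0.0796), milk fat turned to 0.07 and cytosolic ribosomal proteins turned to 0.08, while mitochondrial ribosomal proteins stood at 0.25. Milk fat and cytosolic ribosomal proteins also lost their calls without EEF1D-1893 replicate 2 (-0.17 and -0.10) or EEF1D-1893 replicate 3 (-0.21 and -0.12), and heat shock without EEF1D-1893 replicate 1 (0.15, adjusted p = 0.0526). Cytosolic ribosomal proteins were at -0.01 under quantile normalization (adjusted p = 0.887) and -0.07 with median scaling (adjusted p = 0.088).

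Over all genes 0 passed for EEF1D-1893 in limma (smallest adjusted p = 0.122; 1778 at an unadjusted p under 0.05, 855 higher and 923 lower, or 48.1% higher and 58.8% with median scaling). The nearest by the same criteria were LTBP3, which binds latent TGF-beta, at -0.99 (SE 0.13), TNIK at -1.12 (SE 0.15), QPRT at -1.09 (SE 0.15), NEK6 at -1.04 (SE 0.15) and ERAS at -1.08 (SE 0.15), each at adjusted p = 0.165. With slide as a block 1855 genes passed, 825 up and 1030 down, these 5 among them (adjusted p between 0.0238 and 0.0265). Leaving out control replicate 1, control replicate 2 or EEF1D-1357 replicate 3 gave 25, 1855 or 1 genes. The groups were apart in 28.3% of genes, where chance gives 20% if the arrays can be exchanged, and the same limit holds for control replicate 1.

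Between the shRNAs, EEF1D-1357 arrays as a group had lower cell division genes and higher inflammatory, lipid and interferon-stimulated genes than EEF1D-1893 arrays. This comparison asks where 2 hairpins against 1 target differ. EEF1D-1357 replicate 3 lay within the range of the EEF1D-1893 arrays for mitosis (0.42), replication (0.26), inflammatory (0.03) and interferon-stimulated genes (-0.18). The same held for cytosolic and mitochondrial ribosomal proteins, whereas for cholesterol synthesis and milk fat it lay above that range. Over all genes its log2 difference had an SD of 0.63 to 0.69 from the EEF1D-1893 arrays, and of 0.71 and 0.73 from its own group. The mitosis list differed by a median of -0.80 with 45 of 45 members below 0 (camera adjusted p = 7.41e-09), with CCNB2 at -1.02 (-0.66 without EEF1D-1357 replicate 1), and the replication list by -0.44 (adjusted p = 2.63e-05). None of the 8 lists that differed was called with an estimated correlation (adjusted p between 0.875 and 0.903). The inflammatory list differed by 0.64 with 30 of 36 above 0 (adjusted p = 1.29e-07). Cholesterol synthesis (0.19, adjusted p = 0.000218), interferon-stimulated genes (0.16, adjusted p = 0.000343, with CMPK2 at 0.50) and milk fat (0.11, adjusted p = 0.00406, with ACSS2 at 0.67) were higher with EEF1D-1357. Cytosolic ribosomal proteins (-0.13, adjusted p = 0.000703) and mitochondrial ribosomal proteins (-0.15, adjusted p = 0.00258) were lower. In these 8 lists 0 members passed over all genes or adjusted over the list alone (limma; 7 inflammatory genes higher, 1 lower and 0 mitosis genes at an unadjusted p under 0.05). Among the amino acid transporters (-0.19, adjusted p = 0.55), SLC6A14 rose by 1.62 and SLC7A6 fell by 0.74 adjusted over the list alone.

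With slide as a block, where each shRNA is set against the control on its own slide, 1 list was called, cholesterol synthesis (median 0.88, adjusted p = 0.00975). Mitosis stood at -0.50 (adjusted p = 0.0627), inflammatory genes at 0.22, interferon-stimulated genes at 0.02 and milk fat at 0.51, while replication (0.08), cytosolic ribosomal proteins (0.23) and mitochondrial ribosomal proteins (0.10) turned upwards. Without EEF1D-1357 replicate 1 the mitosis median was -0.42, and replication (-0.25, adjusted p = 0.0571), interferon-stimulated genes (0.03, adjusted p = 0.0581), cytosolic ribosomal proteins (-0.11, adjusted p = 0.0571) and mitochondrial ribosomal proteins (-0.13, adjusted p = 0.0581) were not called. Without EEF1D-1357 replicate 3 the medians were -1.30 for mitosis, -0.71 for replication, 0.40 for interferon-stimulated genes and 0.18 for milk fat. Without EEF1D-1893 replicate 3 mitosis was -0.51 and replication -0.25. The inflammatory median was 0.31, 0.41 or 0.38 without EEF1D-1357 replicate 2 or EEF1D-1893 replicate 1 or 2, and milk fat was 0.07, 0.17 or 0.06, the last not called (adjusted p = 0.0596). Mitochondrial ribosomal proteins were also not called without EEF1D-1357 replicate 2 (-0.11, adjusted p = 0.111), and cytosolic ribosomal proteins stood at -0.03 under quantile normalization (adjusted p = 0.494) and -0.07 with median scaling.

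EEF1D itself differed by -0.19 (SE 0.32) between the shRNAs (adjusted p = 0.889), and the sign turned with slide as a block (0.79, SE 0.50) and without EEF1D-1357 replicate 3 (0.08). In the slide block the turn came from the added difference between control replicates 1 and 2, at 7.11 and 6.14. No gene passed over all genes (0 in limma, smallest adjusted p = 0.262; 809 at an unadjusted p under 0.05, 325 higher and 484 lower, where chance gives 630.9). A mixed split, with EEF1D-1357 replicates 1 and 2 beside EEF1D-1893 replicate 1, gave 908 genes at that threshold, so the 809 do not stand out. The share of higher genes among the 809 was 40.2% and became 59.4% with median scaling. The nearest by the same criteria were the metalloprotease ADAM19 at -1.62 (SE 0.21) and HMGB3 at 1.24 (SE 0.17). The beta-defensin EBD stood at 3.86 (SE 0.50) and the ectonucleotidase ENPP3 at 2.91 (SE 0.45). Their adjusted p lay between 0.394 and 0.688. With slide as a block 6 genes passed, 2 up and 4 down. The groups were apart in 21.6% of genes, where chance gives 10% if the arrays can be exchanged, though each group lay on its own slide.

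Genes shifted by both shRNAs in the same direction were counted across the contrasts, which share the 2 controls. Over all genes 0 were called with both in limma, and at an unadjusted p under 0.05 there were 999 in the same direction among 1001 shared. Independence gives 145.5 and the simulations of unchanged groups with shared controls give a median of 196.5. In the simulations every array had the same spread per gene, whereas the real controls differed from each other more than arrays with the same shRNA. A count above the simulated one can therefore come from the shared controls alone, and agreement of the shRNAs cannot be read from it. The correlation over genes of the fold changes was 0.659, against 0.600 in the simulations. Where each shRNA had its own control, it was 0.109 with the controls of the same slides and -0.029 with the controls crossed. Leaving out control replicate 1 or 2 gave 20 or 1563 genes called with both. NEK6 and ERAS were among the 5 nearest to passing for each shRNA, as was QPRT.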

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

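Of the tests in this part, the slide tests, the splits within the slides, the test of control replicate 1 alone and the test of variation between cultures or arrays were chosen only after the result was seen. The 8 results here are gene lists whose response differed between the shRNAs by a direct test of EEF1D-1357 against EEF1D-1893 with camera. The differences in median log2 were -0.80 for mitosis, 0.64 for inflammatory genes, -0.44 for DNA replication, 0.19 for cholesterol synthesis, 0.16 for interferon-stimulated genes, -0.13 for cytosolic ribosomal proteins, -0.15 for mitochondrial ribosomal proteins and 0.11 for milk fat synthesis. In all but cholesterol synthesis and milk fat, EEF1D-1357 replicate 3 lay within the range of the EEF1D-1893 arrays. None of the 8 was called with an estimated correlation (adjusted p between 0.875 and 0.903). With slide as a block 1 was called, cholesterol synthesis, and replication (0.0841), cytosolic ribosomal proteins (0.228) and mitochondrial ribosomal proteins (0.0988) turned upwards. That fit adds the difference between the controls to each value, so the call and the turns can come from the controls. Of the 10 splits of the 6 shRNA arrays into 3 and 3, the real one called the most lists, 8 against 7 for the highest other; 10 splits cannot give a share under 0.05. For genes the real split called 0 and the highest other 1, so 10 of 10 splits gave as many, and the same limit holds. For both shRNAs against control, with the shRNA arrays taken as 1 group, 1 of the 28 splits of the 8 arrays into 6 and 2 gave as many lists, the real one, with 11 against 10 for the highest other. These splits pass over the slides, within which alone the arrays can be exchanged. Of the 16 splits that take 1 array from each slide, 1 gave as many lists, the real one, with 11 against 10 for the highest other, and 16 splits cannot give a share under 0.05.

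Mitosis genes were lower with EEF1D-1357 than with EEF1D-1893. A trend of the signal with probe GC content or signal level is argued against as the whole cause: its removal moved the genes by a median of 0.05 and left a median difference of -0.74. Variation between single cultures or arrays may be the source, since EEF1D-1357 replicate 3, at 0.42, lay within the range of the EEF1D-1893 arrays, from -0.11 to 0.73. Cultures and arrays cannot be told apart here, as the labels do not say whether replicates came from separate cultures. A difference between the slides stays open and cannot be told apart from the shRNA: the control on slide 1 was lower than that on slide 2 by a median of -0.25 over these genes, and 1 control per slide cannot decide. A difference between the shRNAs in their effect on the cells stays open as well, and was not tested apart from these.

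ER chaperone genes were higher in the shRNA arrays than in both controls. The shift was present within both slides, at 0.26 in the lower, and against control replicate 2 alone, at 0.39. Those values cannot decide on a difference between the slides or on control replicate 1 alone. The pattern had been picked as higher than both controls, so shifts of this sign were largely given. The largest SD of the list's median over arrays with the same shRNA (0.08) was lower, but it holds no variation between controls, and each slide had a single control. A trend with GC content or signal level is argued against as the whole cause, because 0.27 of the 0.30 remained after its removal. A response of the cells to the shRNAs stays a hypothesis, found and tested on the same 8 arrays. Whether it would follow EEF1D loss or the presence of any shRNA is not answered by this design.

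The control arrays differed from each other more than any pair of arrays with the same shRNA, at an SD of 0.83. A difference between the slides is argued against as the whole cause: the covariance of the control difference with the shRNA difference across the same slides was 0.0602, and 0.0394 to 0.0723 with single shRNA arrays left out, against an excess variance of 0.289, if no shRNA difference cancels it. Noise from weaker labelling is argued against as the whole cause, because the SD in the brightest 3155 genes was 0.502, against 0.169 to 0.379 within the shRNA groups. Degraded RNA in control replicate 1 is argued against, because its probes towards the 5′ end were higher against 3′ probes by 0.0524 over 4657 genes, outside the range of the other arrays (-0.0292 to 0.00438) on the side opposite to degradation, so better preserved RNA there stays open. No biological explanation was tested, as the design names none.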

How the results depend on the processing

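In this part the alternatives that leave out 2 arrays, that join the slide block with EEF1D-1357 replicate 3 left out, or that fit each slide on its own were chosen only after the result was seen. The order in all groups of values is both shRNAs, EEF1D-1357 and EEF1D-1893 against control, EEF1D-1357 against EEF1D-1893, and genes called with both shRNAs in the same direction. The count of 0 genes in limma became 719, 28, 1855, 6 and 10 with slide as a block, whose spread holds no control difference by construction, and 729, 24, 2206, 8 and 6 with that block and EEF1D-1357 replicate 3 left out. Of the 719 genes, 497 were also among the 729. Unadjusted p with a 2-fold change gave 318, 467, 308, 186 and 146, a looser threshold. Leaving out control replicate 1 and EEF1D-1357 replicate 3 gave 30, 24, 28, 0 and 21. Single arrays left out gave 0 to 2928, 0 to 2912, 0 to 1855, 0 and 0 to 1563, with 1 control left in the highest cases. An intensity trend with robust prior gave 2 genes for both shRNAs and 2 for EEF1D-1357, the filter on all arrays 3 for EEF1D-1357, and normexp 1 and array weights 13 between the shRNAs; the cause was not tested. All other alternatives gave 0. At the gene level EEF1D kept its negative direction throughout, from -0.23 to -1.48 for the contrasts with control. It passed without control replicate 2 (range with single arrays left out -1.38 to -0.41 for both shRNAs and -1.48 to -0.50 for EEF1D-1357), and in the slide block without EEF1D-1357 replicate 3 at -0.76 for both (adjusted p = 0.0452) and -1.29 for EEF1D-1893 (adjusted p = 0.0297). The 7 lists for both shRNAs became 11 with median scaling, 11 without a filter, 13 with the trend, 11 in the slide block without EEF1D-1357 replicate 3 and 0 with an estimated correlation (5 to 10 with single arrays left out); the 8 between the shRNAs became 1 and 2 in those slide blocks and 0 with an estimated correlation (5 to 11). For both shRNAs, of 22 alternatives, ER chaperones were called in 21, mitosis in 20, inflammatory and heat shock genes in 19 each, ribosomal proteins and replication in 16 each and cholesterol synthesis in 15. Apart from the estimated correlation, these alternatives kept the preset of 0.01, whereas the estimates for these lists ran from 0.07 (heat shock) to 0.81 (mitosis). The calls that held least were heat shock (6 of 24), the synthetases and the stress response (10 of 24 each) with EEF1D-1357, and milk fat (12 of 24) and ribosomal proteins (13 of 24) with EEF1D-1893. Of 674 list values 520 kept their call, 139 lost it and 15 turned: ribosomal proteins to 0.0014 (both shRNAs; -0.388 without control replicate 2) and 0.08 (EEF1D-1893; -0.311) without control replicate 1, and 0.08 with both arrays out; heat shock (EEF1D-1357) to -0.0172 without control replicate 2 (0.216 without 1); milk fat (EEF1D-1893) to 0.0683 without control replicate 1 (-0.369 without 2) and with both arrays out; mitochondrial ribosomal proteins (EEF1D-1893) to -0.0423 in the slide blocks, without control replicate 2 (0.253 without 1) and on their own slide; and between the shRNAs in the slide block, and without EEF1D-1357 replicate 3, ribosomal proteins to 0.23 and 0.17, replication to 0.0841 in the slide block alone, and mitochondrial ribosomal proteins to 0.10 and 0.0913. No named gene had passed over all genes in the main fit, so no call could be lost. Of 2084 values of these genes 1959 kept their sign without passing, 120 newly passed and 5 turned: RPL23 to 0.00764 with normexp, TLR2 to 0.0693 with the mean of probes, RPS23 to 0.0716 in the slide block, and MRPS7 to 0.21 and 0.12 in the slide blocks. The cause of these turns was not tested. Whether replicate numbers pair the arrays cannot be told from 3 arrays per shRNA. The r was 0.107, -0.115 and 0.078 for the same numbers and lay between -0.142 and 0.072 for different ones. As a block the numbers gave 0 genes and an EEF1D value of -0.74 for both shRNAs. No marker list was called in any alternative. Signal over background limits the dim EEF1D probe and the 32 genes at background in all shRNA arrays.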

Other observations

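No test in this part was chosen only after the result was seen. Several genes were well above background on one side only, and their folds are lower bounds. OLR1, a receptor for oxidized LDL, was at least 7.58-fold higher in the shRNA arrays than in the controls (limma adjusted p = 0.0995), the 1 gene found in that direction. In the other direction 32 genes were at background in all 6 shRNA arrays. A fall needed signal well above background in only the 2 controls, whereas a rise needed it in all 6 shRNA arrays. The counts of both directions therefore cannot be compared. TMEM74 was at least 4.22-fold lower (adjusted p = 0.202) and the G protein subunit GNAO1 at least 3.85-fold lower (adjusted p = 0.0526). None of the 3 passed here, whereas OLR1, TMEM74 and GNAO1 passed with slide as a block (adjusted p = 0.0314, 0.0359 and 0.0183). Without control replicate 2 OLR1 and GNAO1 passed (adjusted p = 0.0141 for both), and the fitted log2 change of TMEM74 moved from -2.83 to -1.09 (to -4.57 without control replicate 1).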
